A study of Homo sapiens with 86 samples.

How the data were processed

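Gastrocnemius muscle RNA of 86 libraries was compared between Control (24 libraries), peripheral artery disease (PAD, 32), chronic kidney disease (CKD, 16) and both diseases (PAD+CKD, 14), with groups taken from the sample labels. Per the labels' protocols, RNA was extracted with a Zymo Direct-Zol kit and polyadenylated RNA was sequenced. The authors deposited TPM values, which scale the transcripts of each gene to its length and to a total of 1000000 per library, as a single file. Reads were trimmed with Trimmomatic 0.36 and aligned with STAR 2.5.2b to GRCh38, per the submitters' processing notes. The tool that counted reads per gene, the gene annotation and whether counting used the strand are not given in the sources used here. Values of overlapping genes, of genes with an antisense partner and of near-identical copies are therefore uncertain.

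The table held 57500 genes, 485 of them without a name and 1517 with a name that another gene also had. Each library was checked to sum to 1000000 TPM (largest deviation 0.0149), so all values are shares and a rise of abundant genes lowers all others. TPM keeps no sequencing depth, so the depth per library and the counting error are unknown. No 2 columns were identical, and the highest Spearman correlation between 2 libraries was 0.933. Gene identifiers were matched to GENCODE v29 on GRCh38 for coordinates and gene types, with 56898 matched and 602 not. The genes of the 2 mitochondrial ribosomal RNAs were not among the values analysed. The labels give no age, treatment, batch or other covariate that was used here, and replicate numbers follow the order of accession and pair nothing.

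From the deposited TPM, log2(TPM + 1) was computed. Fold changes on this scale understate the change of genes with low values. Genes with at least 1 TPM in at least 14 libraries were kept, which left 16805, of which 12121 were protein-coding. All 4 groups were fitted together in limma 3.58.1, which shares 1 estimate of the spread, with empirical Bayes moderation (trend and robust options). The 6 pairwise comparisons and the interaction, (PAD+CKD minus PAD) minus (CKD minus Control), were read from this fit, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The comparisons, tests, 37 gene lists, 13 cell type lists, 37 key genes and a first set of other settings were fixed before the data were examined. Lists were tested with camera, which compares the genes of a list with all other genes. A call up or down is therefore relative to the other genes. Camera was run at its preset correlation of 0.01 and again with an estimated correlation. The fry test, which takes the genes of a list on their own, called 0 lists in all 7 comparisons. When libraries were regrouped at random, camera with the preset correlation called a median of 11 to 18 of the 50 lists, so a call at that setting alone is weak evidence. The estimated correlation called none in the main setting. Within each list, p-values were also adjusted over the list alone. Over all 16805 genes the median log2 fold change was 0.069 in PAD, 0.045 in CKD and 0.013 in PAD+CKD, each against Control. It was −0.049 in PAD+CKD against PAD, −0.032 in PAD+CKD against CKD, 0.024 in PAD against CKD and −0.101 for the interaction. Counts of list genes higher or lower, and small list medians, partly reflect these shifts.

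Named genes followed a rule fixed beforehand. It takes, among genes called, the 10 highest and 10 lowest fold changes, then up to 4 genes of each list with the smallest p, called ones first, and the key genes. Where fewer than 5 genes were called, the 5 with the smallest p were named as not called. For the interaction, the rule takes the 5 highest and 5 lowest fold changes among genes called. Some genes that the rule takes are not reported here. Of the key genes 33 passed the filter, and AHRR, FGF21, IL6 and KL did not. LYNX1 as a call, and genes named in CKD replicate 1, were chosen after their values were seen. The share of TPM from the 13 mitochondrially encoded proteins and the share of MYH7 among MYH7, MYH2 and MYH1 were compared by two-sided permutation tests of the difference in means with 100000 resamples, adjusted over 6 pairs.

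The other settings fixed beforehand were an estimated correlation, a pseudocount of 0.1, no filter, median-of-ratios scaling, removal of mitochondrially encoded genes, array quality weights, a fit of only the 2 groups compared, and fits without 5 libraries whose median correlation with the others lay more than 4 median absolute deviations below the median (3 PAD, 1 CKD and 1 PAD+CKD). Others were fits with 1 of 3 kinds of covariate: the library number (a spline with 3 degrees of freedom, as a stand-in for the order of collection), a score of sex chromosome genes, or the scores of the adipocyte and fibroblast lists. For the shares they were medians, all mitochondrially encoded genes and a score of slow minus fast fibre genes. After the data had been seen, further settings were added, 51 when counted for each result they apply to: leaving out CKD replicate 1, alone or together with the library number or with the adipocyte and fibroblast scores, the last also with median-of-ratios scaling, protein-coding genes only, and list scores per library compared by permutation tests. Other splits of the libraries into groups of the same sizes were drawn 100 times per comparison, the real split included. Correlations of fold changes that share the Control libraries were set against 100 regroupings without effect.

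The fit was tested on simulated data, in which residuals of the real libraries were shuffled, whole libraries at a time, in 5 sets. Of the 16805 genes, 200 were changed by a known fold on the log2(TPM + 1) scale. They were drawn only from genes whose mean on this scale lay above that of 5 TPM. The shares recovered therefore do not cover genes with lower values. They also hold only for 200 genes changed at once, which makes the Benjamini-Hochberg threshold easier to pass than when few genes change. A lack of calls in the real data therefore does not exclude changes of 1.5- or 2-fold. At 1.5-, 2- and 3-fold, 84.9%, 96.2% and 99.7% of changed genes were recovered for PAD against Control. The same shares were 76.5%, 96.8% and 99.4% for CKD against Control, 64.4%, 92.7% and 99.4% for PAD+CKD against Control, 68.4%, 95% and 98.5% for PAD+CKD against PAD, 62.7%, 93.8% and 97.9% for PAD+CKD against CKD, 80.7%, 96.1% and 99% for PAD against CKD, and 43.7%, 84.8% and 96.5% for the interaction. False calls per set averaged 19.6 (0 to 84) for PAD against Control, or 9.51% of calls, 10.2 (5.51%) for PAD+CKD against PAD and 2 to 2.6 (1.16% to 1.58%) for the other 5 comparisons. When each gene was shuffled on its own, 3.05% to 5.92% of calls were false. The work used R 4.3.3 with the data.table package, version 1.17.8, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.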

Results

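RNA from the gastrocnemius, a muscle of the calf, was sequenced in 86 libraries. Of these, 24 came from controls, 32 from patients with peripheral artery disease (PAD, in which the arteries of the leg are narrowed), 16 from patients with chronic kidney disease (CKD) and 14 from patients with both diseases (PAD+CKD). The comparisons ask how the calf muscle transcriptome differs with each disease, and whether the difference that goes with CKD depends on PAD. The deposited table gave the abundance of 57500 genes as TPM, the share of each gene's transcripts scaled to a total of 1000000 per library. TPM keeps no sequencing depth, so the depth of each library is unknown and no counting error can be given. On average 23840 ± 1671 genes (SD, n = 24) had a value above 0 in Control, 24172 ± 968 (n = 32) in PAD, 23818 ± 1613 (n = 16) in CKD and 24001 ± 929 (n = 14) in PAD+CKD. It was assumed that there was 1 library per specimen, and the labels do not say whether the specimens came from separate people. The p-values therefore set group differences against the spread between these libraries, which need not be the spread between people.

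CKD replicate 1 stood apart from the other 85 libraries. Its median Spearman correlation with the libraries of each group lay between 0.605 and 0.614, whereas the lowest median among the other 85 was 0.828. Of the 8 measured list genes of T and natural killer (NK) cells, 7 were above the median of the other CKD libraries. GZMB, a protease of killer lymphocytes, was at 890 TPM against at most 7.30 TPM elsewhere, and CD3D, a chain of the T cell receptor complex, at 107 TPM against at most 6.92, but CD4 ranked 59 of 86 (0.675 TPM). ACTA1, the skeletal muscle actin, was at 3025 TPM in this library and at a median of 72283 TPM in the other CKD libraries. CKM, the muscle creatine kinase, was at 1371 TPM against a median of 27643. Values without this library (n = 15 for CKD) are given beside many of the CKD results.

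In PAD, most measured genes for fatty acid use had lower means than in Control, though no single gene passed and the list was called only with the preset correlation. Of 28 measured genes of fatty acid uptake and oxidation, 24 had a lower mean log2 value (median log2 fold change −0.10). ACSL1, which activates long-chain fatty acids, was at 95.2 ± 33.2 TPM (SD, n = 32) in PAD and 142 ± 84.4 TPM (n = 24) in Control, and lay below the Control median in 28 of 32 PAD libraries. Its log2 fold change was −0.46 (SE 0.19). FABP3, the fatty acid carrier of heart and skeletal muscle, was lower by a log2 fold change of −0.52 (SE 0.23), and PLIN5, a coat protein of lipid droplets, by −0.63 (SE 0.24). Glucocorticoid target genes were lower in 12 of 14 cases (median −0.23), among them KLF15, a metabolic transcription factor (−0.61, SE 0.23), FKBP5, a co-chaperone of the glucocorticoid receptor (−0.72, SE 0.33), and GLUL, the glutamine synthetase (−0.52, SE 0.24).

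Developmental and fast fibre genes and matrix genes had mostly higher means in PAD, and slow fibre genes mostly lower ones. All 10 measured genes of the developmental sarcomere, which are used in embryonic or regenerating fibres and include cardiac forms, had higher means in PAD (median 0.65), such as TNNT2 (0.78, SE 0.33), MYL5 (0.59, SE 0.28) and ACTC1 (0.84, SE 0.47). All 14 genes of the fast fibre sarcomere were higher (median 0.35), for example the troponins TNNI2 (0.62, SE 0.27) and TNNT3 (0.65, SE 0.28) and the tropomyosin TPM1 (0.52, SE 0.26). Of 12 slow fibre genes, 11 were lower (median −0.12), with ATP2A2, the calcium pump of slow fibres, at −0.37 (SE 0.19), MYL3 at −0.34 (SE 0.19) and LGI1 at −0.20 (SE 0.11). Fibrillar matrix genes were higher in 29 of 30 cases (median 0.33). Examples were TIMP1, an inhibitor of matrix proteases (0.58, SE 0.26), and the collagens COL6A3 (0.34, SE 0.15) and COL5A1 (0.42, SE 0.19).

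All 21 interferon response genes were higher in PAD (median 0.22), and IFIT2 passed Benjamini-Hochberg adjustment when adjusted over the list alone (0.40, SE 0.11; above the Control median in 26 of 32 libraries). IFIT1 (0.39, SE 0.14) and the immunoproteasome subunit PSMB8 (0.37, SE 0.17) did not. All 46 cytosolic ribosome genes were higher (median 0.19), including RPL8 (0.20, SE 0.09). In the list of inflammatory cytokines and NF-kB targets, 10 of 12 genes were higher (median 0.20), and the adhesion molecule ICAM1 passed when adjusted over the list alone (0.45, SE 0.14), while CXCL10 (0.47, SE 0.24) and VCAM1 (0.25, SE 0.15) did not. Among regulators of mitochondrial biogenesis, 12 of 21 were lower (median −0.04), with ESRRG at −0.31 (SE 0.10), TFB2M at −0.23 (SE 0.11) and PPARGC1A, a coactivator that drives mitochondrial biogenesis, at −0.34 (SE 0.15). Of the key genes fixed beforehand, COL1A1 (0.80, SE 0.39), VEGFA, the main angiogenic growth factor (−0.42, SE 0.21), GDF15 (0.32, SE 0.14) and PPARGC1A had unadjusted p below 0.05, and their adjusted p was 0.326 when adjusted over the list alone.

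By limma, 0 of 16805 genes passed an adjusted p of 0.05 in PAD against Control, and 1454 had an unadjusted p below 0.05, 1233 higher and 221 lower in PAD. With median-of-ratios scaling the split was 823 higher and 811 lower. CKD replicate 1 enters the shared estimate of the spread in this fit too. Without it 1938 genes had an unadjusted p below 0.05 (1596 higher, 342 lower), and in a fit of only the 2 groups 2019 did (1664 higher, 355 lower). The 5 genes with the smallest p, none called, were AL080248.1 (−0.85, SE 0.18; adjusted p = 0.151), AC009084.1 (−0.89), AL031587.5 (0.42), PARD3-AS1 (0.63) and ANKRD24 (0.42). The camera test with its preset correlation called 15 of 50 gene lists, 5 up and 10 down. Its adjusted p was 1.7e-09 for fatty acid genes and for cytosolic ribosome genes, 7.2e-06 for glucocorticoid targets, 6.4e-05 for slow fibre genes, 0.00028 for mitochondrial biogenesis, 0.00064 for fibrillar matrix, 0.0013 for interferon response, 0.0368 for the developmental and 0.0485 for the fast fibre sarcomere. The NF-kB list was not called (adjusted p = 0.258). With an estimated correlation no list was called, and the adjusted p was 0.859 for the lists named that were lower and 0.980 for those that were higher. The call of the developmental sarcomere list was lost in 7 alternatives (median 0.364 and adjusted p = 0.287 with array quality weights, 0.349 and 0.255 without the low-correlation libraries), that of the fibrillar matrix and crosslinking list in 4 and that of the fast fibre sarcomere list in 2 (0.0836 with the library number covariate). The matrix list was not called with array quality weights (median 0.195, adjusted p = 0.162), nor with the adipocyte and fibroblast list covariates (median 0.116, adjusted p = 0.0679). Those covariates remove part of the matrix difference by construction, because DCN, LUM, COL15A1 and LOX are in both the fibroblast and the matrix list. Fibroblast markers, higher in 15 of 17 cases (median 0.10, adjusted p = 0.752), and macrophage markers, higher in 16 of 18 (median 0.18, adjusted p = 0.432), were not called in PAD against Control. The median over all 16805 genes was 0.069 in this comparison.

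**Figure D1:**
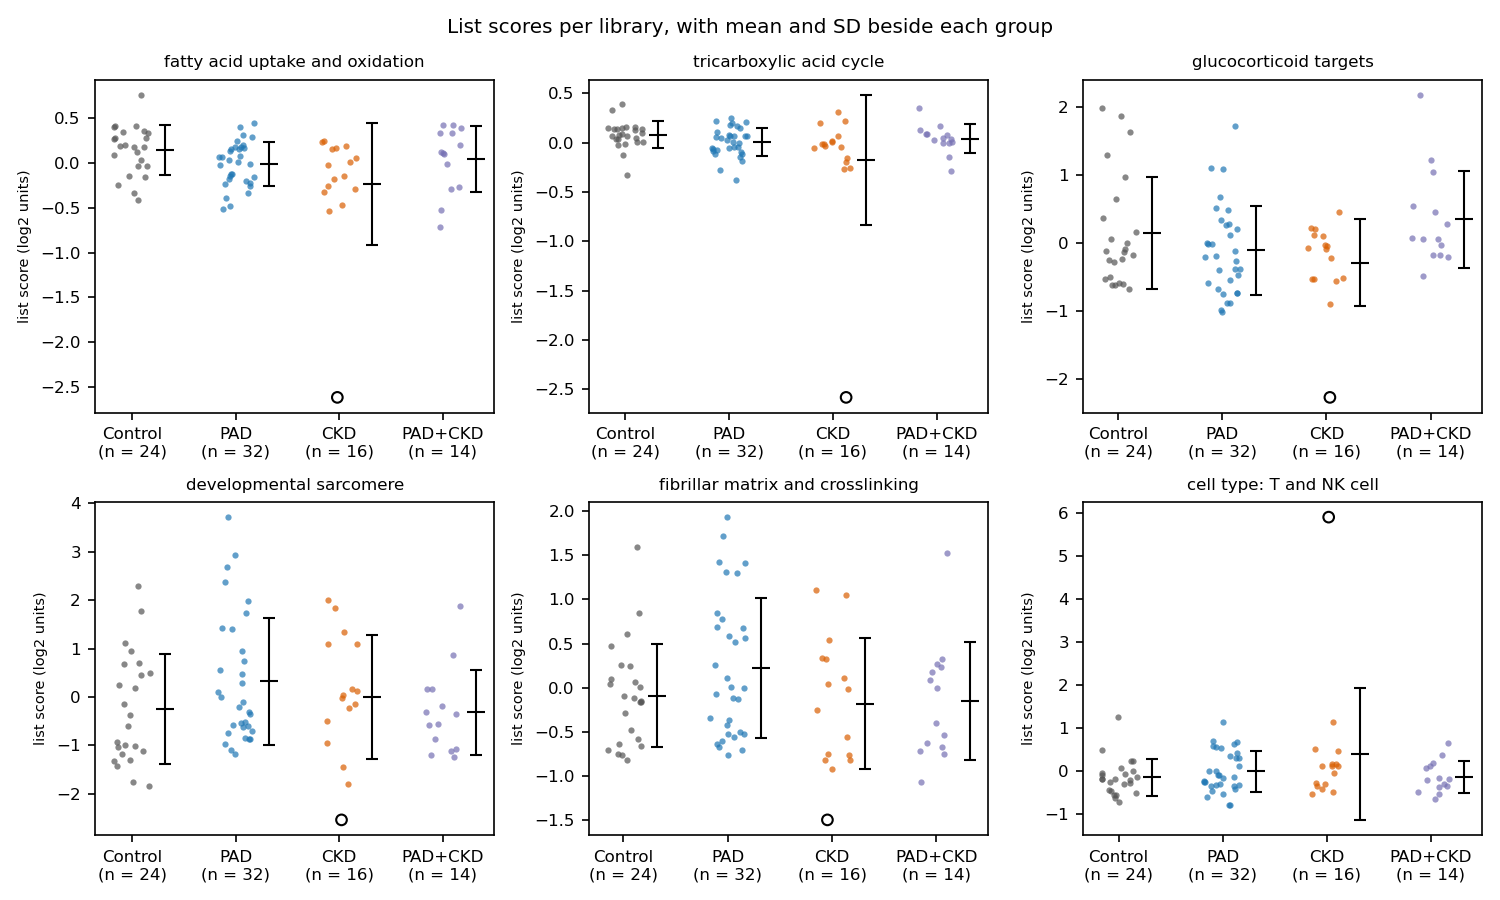
Scores of 6 gene lists per library (the mean over a list's genes of the log2 difference from the mean of all 86 libraries, y axis) by group (x axis); points are libraries, bars the mean and SD, and the open circle is CKD replicate 1. The fatty acid score averaged 0.144 ± 0.274 in Control, −0.0086 ± 0.247 in PAD, −0.238 ± 0.682 in CKD (−0.079 ± 0.259 without CKD replicate 1) and 0.044 ± 0.364 in PAD+CKD.

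In CKD, most measured genes of fatty acid use and of the tricarboxylic acid cycle had lower means than in Control. Of the 28 genes of fatty acid uptake and oxidation, 27 had lower means (median −0.33), and 25 without CKD replicate 1 (median −0.18). FABP3 (ENSG00000121769, chromosome 1, 31365625 to 31376850 in GRCh38) was at 547 ± 334 TPM (SD, n = 16) in CKD and 912 ± 374 TPM (n = 24) in Control, below the Control median in 13 of 16 libraries. Its log2 fold change was −0.98 (SE 0.27), and −0.72 without CKD replicate 1. ACSL1 was at −0.78 (SE 0.22; −0.60 without that library) and ETFDH, which passes electrons from fatty acid oxidation to the respiratory chain, at −0.54 (SE 0.16; −0.31 without it). Adjusted over the list alone, 13 fatty acid genes were lower, and 3 without CKD replicate 1. Tricarboxylic acid cycle genes were lower in 18 of 19 cases (median −0.27), and in 16 without the library (median −0.08), such as PDHA1 (−0.31, SE 0.09; −0.20 without it), MDH1 (−0.45, SE 0.14; −0.29) and DLAT (−0.42, SE 0.14; −0.30). The 8 that passed when adjusted over the list alone became 0 without it.

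Differences in respiratory chain subunits rested in large part on CKD replicate 1. Nuclear subunits of complexes II and III were lower in 13 of 13 cases (median −0.24), and in 12 without CKD replicate 1 (median −0.09), for example SDHC (−0.37, SE 0.13; −0.21 without it), SDHB (−0.30, SE 0.11; −0.13) and UQCRFS1 (−0.24, SE 0.10; −0.10). ATP synthase subunits were lower in 14 of 15 (median −0.12), and in 11 without it (median −0.06), with ATP5MC1 at −0.37 (SE 0.12; −0.24 without it), ATP5F1A at −0.32 (SE 0.10; −0.18) and ATP5MC3 at −0.33 (SE 0.11; −0.23). Adjusted over the list alone, 6 of them were lower, and 0 without that library. Complex I subunits were lower in 33 of 37 (median −0.13), but in 20 of 37 without the library, where their median was −0.003. NDUFS1 (−0.39, SE 0.14; −0.22 without it), NDUFA5 (−0.25, SE 0.10; −0.14) and NDUFB5 (−0.19, SE 0.08; −0.12) had the smallest p. Among 21 regulators of mitochondrial biogenesis, 15 were lower (median −0.11), and 11 without it (median −0.05), and 3 passed when adjusted over the list alone, against 0 without it. ESRRA was at −0.44 (SE 0.13; −0.27 without it), ESRRG at −0.39 (SE 0.12; −0.32) and MFN2, which fuses mitochondria, at −0.43 (SE 0.14; −0.25). All 12 slow fibre genes were lower (median −0.31), and 8 without CKD replicate 1 (median −0.05), such as MYL3 (−0.67, SE 0.23; −0.43 without it), ATP2A2 (−0.52, SE 0.22; −0.23) and TPM3 (−0.38, SE 0.17; −0.17).

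Interferon response genes were higher in CKD in 21 of 21 cases (median 0.37, and 0.24 without CKD replicate 1). MX1 was at 0.57 (SE 0.20; 0.35 without it), OAS1 at 0.52 (SE 0.18; 0.26) and IFI44L at 0.48 (SE 0.17; 0.31). Of these genes, 9 passed when adjusted over the list alone, and 0 without that library. Genes of T and NK cells were higher in 7 of 8 cases (median 0.62), and without the library, where 6 were higher, the median was 0.18 and the list was not called (adjusted p = 0.786). GZMA was at 0.69 (SE 0.26; 0.32 without it), CCL5 at 0.93 (SE 0.35; 0.45) and NKG7 at 0.78 (SE 0.32; 0.36). The 3 measured globin genes of red blood cells, HBB (1.21, SE 0.52), HBA1 (0.95, SE 0.45) and HBA2 (0.92, SE 0.53), had a median of 0.95, and of 1.29 without CKD replicate 1, where all 3 passed when adjusted over the list alone. The score of this list per library averaged 0.656 in CKD with a median of 0.044 and a highest value of 6.47, so a few high libraries carry much of the mean. The call was lost in 4 alternatives, among them the library number covariate (median 0.468, adjusted p = 0.232) and the adipocyte and fibroblast list covariates (median 1.04, adjusted p = 0.104). HBA1 and HBA2 are near-identical copies, so the split between them is uncertain.

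Glucocorticoid targets had lower means in CKD in 13 of 14 cases (median −0.42), and in 12 without CKD replicate 1 (median −0.28), with KLF15 at −0.69 (SE 0.28), ZBTB16 at −0.43 (SE 0.21; −0.27 without it) and FKBP5 at −0.77 (SE 0.39). Not all libraries shared this: KLF15 and ZBTB16 each lay below the Control median in 10 of 16 CKD libraries, and FKBP5 in 12. Adipocyte marker genes were lower in 11 of 16 (median −0.34, and −0.24 without the library). Among them were LPL, which frees fatty acids from lipoproteins (−0.79, SE 0.27), LIPE, the hormone-sensitive lipase (−0.50, SE 0.17), and PLIN4 (−0.59, SE 0.23; −0.30 without it). All 46 cytosolic ribosome genes were higher (median 0.21 with and without the library), including RPS19 (0.35, SE 0.16), RPS9 (0.27, SE 0.12) and RPL24 (0.27, SE 0.13). Among the key genes, VEGFA was at 20.2 ± 10.8 TPM in CKD (n = 16) and 32.8 ± 16.3 TPM in Control (n = 24), a log2 fold change of −0.73 (SE 0.25; adjusted p = 0.140 when adjusted over the list alone). PPARGC1A was at −0.45 (SE 0.18), TRIM63, a ubiquitin ligase of muscle wasting, at −0.83 (SE 0.35; −0.55 without CKD replicate 1), MYH7, the slow myosin heavy chain, at −0.40 (SE 0.20; −0.13) and GDF15 at 0.43 (SE 0.17).

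By limma, 1 of 16805 genes passed in CKD against Control: AC131097.2 (ENSG00000216921, a protein-coding gene of chromosome 2, 241893985 to 241902551 in GRCh38), which fell. It was at 2.25 ± 1.73 TPM (n = 16) in CKD and 19.7 ± 26.4 TPM (n = 24) in Control, below the Control median in 16 of 16 libraries, with a log2 fold change of −2.06 (SE 0.41; adjusted p = 0.0471). Without CKD replicate 1 its log2 fold change was −1.96 and its adjusted p 0.178. The next smallest p belonged to ZNF143 (0.37, SE 0.08; adjusted p = 0.286), AC073575.2 (0.75), LYNX1 (−0.59) and AL391840.1 (0.82), none of them called. At an unadjusted p below 0.05 there were 1755 genes, 1247 higher and 508 lower, and 1091 higher and 1269 lower with median-of-ratios scaling. With the adipocyte and fibroblast list scores as covariates limma called 306 genes, 290 of them higher, and 418 (408 higher) when CKD replicate 1 was also left out, of which 221 were among the 306. With median-of-ratios scaling added, 2 were called, AC131097.2 and LYNX1. The fits that combine these settings were chosen after the 306 had been seen.

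The camera test with its preset correlation called 33 of 50 lists in CKD against Control, 6 up and 27 down. Its adjusted p was 4.0e-19 for fatty acid genes, 6.4e-14 for the tricarboxylic acid cycle, 2.9e-11 for complex I, 1.2e-10 for complexes II and III, 4.8e-09 for ATP synthase, 4.6e-06 for mitochondrial biogenesis, 2.2e-06 for slow fibre genes, 2.7e-08 for interferon response, 3.5e-06 for glucocorticoid targets, 1.1e-05 for adipocyte genes, 3.6e-09 for cytosolic ribosome, 0.00205 for T and NK cells and 0.020 for red blood cells. With an estimated correlation no list was called, and other splits of the same libraries, drawn at random, gave a median of 18 called lists with the preset correlation. The estimated adjusted p was 0.260 for fatty acid genes, 0.315 for complex I, 0.354 for T and NK cells and red blood cells, 0.439 for cytosolic ribosome and 0.286 for the others named. Without CKD replicate 1 it was 0.0786 for the fatty acid uptake and oxidation list. With the adipocyte and fibroblast list covariates added, a setting chosen after the data had been seen, this list was called with an estimated correlation (adjusted p = 0.0171). That fit also called the adipocyte and fibroblast lists, themselves the covariates (medians 0.0056 and −0.0011, adjusted p = 0.0128 and 0.0354). Its calls are therefore weak evidence. With median-of-ratios scaling added, the fatty acid list was not called with an estimated correlation. With the preset correlation the interferon response list was not called with array quality weights (adjusted p = 0.105), nor were glucocorticoid targets with the library number covariate (0.0997; median −0.0023 with CKD replicate 1 also left out). The fatty acid score per library was lower in CKD than in Control by −0.38 (two-sided permutation test, 100000 resamples, p = 0.00426, adjusted p = 0.178 over 50 lists), and 3 of 16 CKD libraries lay above the Control median. Without CKD replicate 1 the difference was −0.22 (p = 0.0168, adjusted p = 0.377).

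**Figure D2:**
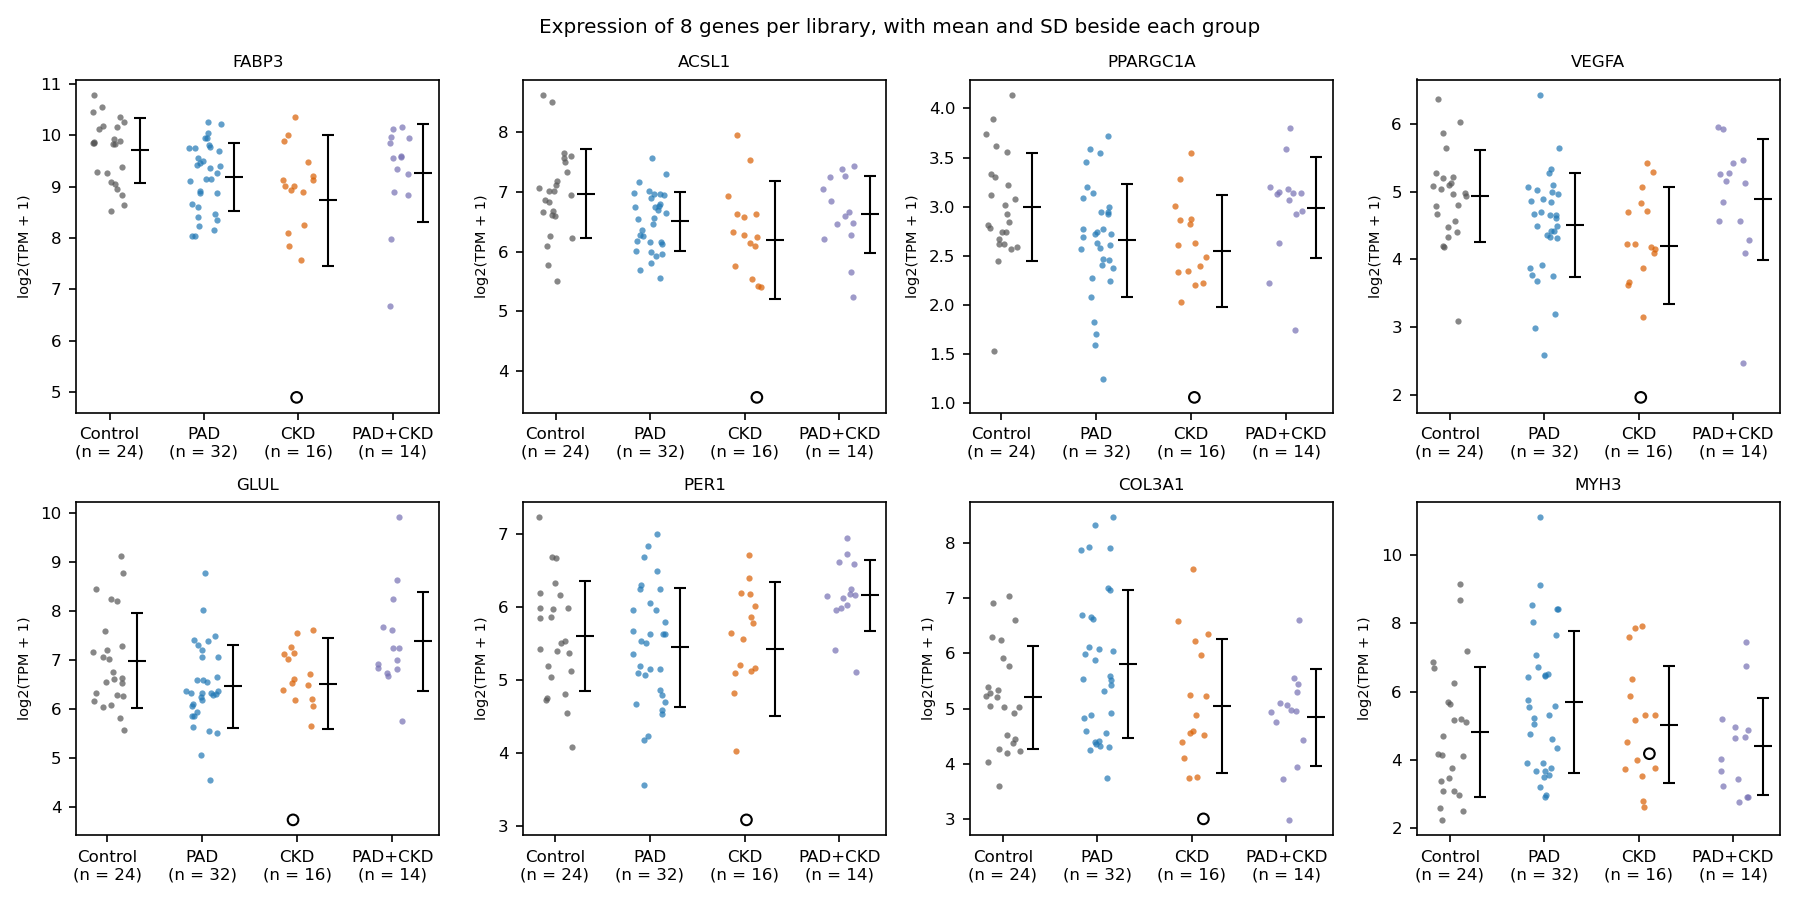
Abundance of 8 genes per library as log2(TPM + 1) (y axis) by group (x axis); points are libraries, bars the mean and SD, and the open circle is CKD replicate 1. Mean FABP3 was 912 TPM in Control, 644 in PAD, 547 in CKD and 713 in PAD+CKD, and mean GLUL was 160, 105, 105 and 221 TPM in the same order.

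Muscle with both diseases was then compared with Control. All 46 cytosolic ribosome genes were higher in PAD+CKD (median 0.18), such as RPS27 (0.30, SE 0.14) and RPL8 (0.23, SE 0.12). All 12 slow fibre genes were lower (median −0.18), including LGI1 (−0.24), MYL3 (−0.30, SE 0.24) and TPM3 (−0.22, SE 0.17). Fatty acid genes were lower in 20 of 28 cases (median −0.11), with SLC25A20, which carries acylcarnitines into mitochondria, at −0.28 (SE 0.15) and below the Control median in 13 of 14 libraries, FABP3 at −0.44 (SE 0.28) and PLIN5 at −0.44 (SE 0.30). Immediate early genes, which respond within minutes and also to tissue handling, were higher in 15 of 18 cases (median 0.16). EGR1 was at 39.9 ± 61.1 TPM (n = 14) against 12.4 ± 10.7 TPM in Control (n = 24), a log2 fold change of 1.04 (SE 0.40), KLF6 at 0.52 (SE 0.18) and ZFP36 at 0.53 (SE 0.30). GDF15 was the only key gene with an unadjusted p below 0.05 (0.38, SE 0.18; adjusted p = 0.979 when adjusted over the list alone).

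By limma, 0 of 16805 genes passed in PAD+CKD against Control, and 491 had an unadjusted p below 0.05, 312 higher and 179 lower. The smallest p belonged to AL021068.1 (−0.51, SE 0.13), SERPINA5 (−1.41, SE 0.37), PTPN20 (−0.63, SE 0.17), RCAN1, an inhibitor of calcineurin (−0.44, SE 0.12), and MIR320E (1.76, SE 0.51), each with an adjusted p above 0.999. The camera test called 4 of 50 lists, cytosolic ribosome (adjusted p = 4.5e-13), slow fibre (0.0119), fatty acid (0.0187) and immediate early genes (0.0488), and none with an estimated correlation (adjusted p = 0.983 for all 4). Median-of-ratios scaling left only the ribosome list called, with adjusted p of 0.0523 for slow fibre genes and 0.0791 for the other 2, while the medians stayed about as large (−0.19 for slow fibre, −0.12 for fatty acid and 0.16 for immediate early genes). In all, the fatty acid call was lost in 6 alternatives and that of immediate early genes in 7. With the library number covariate the fatty acid uptake and oxidation list was at 0.913, and without CKD replicate 1, which enters the shared estimate of the spread, immediate early genes were at 0.0507 with a median still of 0.16.

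Between PAD+CKD and PAD, glucocorticoid target genes had mostly higher means with both diseases, a difference called for the list only with the preset correlation. Of 14 such genes, 13 had higher means in PAD+CKD than in PAD (median 0.48). GLUL was at 221 ± 232 TPM (n = 14) in PAD+CKD and 105 ± 78.8 TPM (n = 32) in PAD, a log2 fold change of 0.91 (SE 0.29), above the PAD median in 13 of 14 libraries. PER1, a clock gene that glucocorticoids induce, was at 0.71 (SE 0.24) and KLF15 at 0.71 (SE 0.27). Adjusted over the list alone, 2 of the 14 were higher, and 3 without CKD replicate 1. IRS2, an adaptor of the insulin receptor, was above the PAD median in 14 of 14 libraries (0.75, SE 0.22) and passed when adjusted over its list alone. Its list of insulin and glucose uptake genes was higher in 12 of 17 cases (median 0.03), with PIK3R1 at 0.53 (SE 0.20) and the glucose transporter SLC2A4 at 0.32 (SE 0.19). Immediate early genes were higher in 13 of 18 (median 0.18), 2 of them when adjusted over the list alone, with EGR1 at 1.13 (SE 0.38), ZFP36 at 0.81 (SE 0.28) and NR4A1 at 0.65 (SE 0.28).

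Most matrix and developmental sarcomere genes had lower means in PAD+CKD than in PAD, and these lists too were called only with the preset correlation. Fibrillar matrix genes were lower in 28 of 30 cases (median −0.34). COL3A1, the collagen III chain, was at 32.8 ± 21.4 TPM (n = 14) against 86.6 ± 92.3 TPM (n = 32), a log2 fold change of −0.97 (SE 0.36). COL5A1 was at −0.59 (SE 0.23), TIMP1 at −0.72 (SE 0.30) and COL1A1 at −0.98 (SE 0.47). All 10 developmental sarcomere genes were lower (median −0.63), with MYH3, the embryonic myosin heavy chain, at −1.30 (SE 0.59), MYL4 at −0.74 (SE 0.38) and TNNT2 at −0.71 (SE 0.40). All 15 satellite cell and myogenic genes were lower (median −0.31), among them the fusion proteins MYMK (−0.97, SE 0.34) and MYMX (−0.38, SE 0.16) and the Notch target HEYL (−0.42, SE 0.16). In the NF-kB list, TNFAIP3 (−0.47, SE 0.15) and the chemokine CXCL10 (−0.77, SE 0.28) were lower when adjusted over the list alone, and VCAM1 was at −0.36 (SE 0.18).

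By limma, 0 of 16805 genes passed in PAD+CKD against PAD. At an unadjusted p below 0.05 there were 712, of which 139 were higher and 573 lower, and 418 higher and 460 lower with median-of-ratios scaling. The smallest p belonged to AC092718.4 (−0.85, SE 0.21; adjusted p = 0.998), TCAF1P1 (−0.47), AL162258.2 (−0.58), FADD, an adaptor of death receptors (−0.41, SE 0.12), and LINC00680 (−0.51). No key gene passed when adjusted over the list alone (lowest adjusted p = 0.292, COL3A1). The camera test called 17 of 50 lists, 14 up and 3 down: glucocorticoid targets (adjusted p = 1.4e-11), fibrillar matrix (5.9e-07), immediate early (2.0e-06), satellite cell (0.00023), insulin and glucose uptake (0.00076) and developmental sarcomere genes (0.0084), but not the NF-kB list (0.198). With an estimated correlation none was called, and the adjusted p was 0.264 for glucocorticoid targets, 0.522 for immediate early genes, 0.808 for satellite cell and insulin genes and 0.941 for matrix and developmental genes. The call of the fibrillar matrix and crosslinking list was lost with the adipocyte and fibroblast list covariates (median −0.093, 20 of 30 lower, adjusted p = 0.199). The fibroblast list shares DCN, LUM, COL15A1 and LOX with the matrix list, so this covariate removes part of the matrix difference by construction. The call of the developmental sarcomere list was lost without the low-correlation libraries (0.101). Fibroblast markers (16 of 17 lower, median −0.18, adjusted p = 0.0557) and macrophage markers (17 of 18 lower, median −0.24, adjusted p = 0.0610) were not called. The glucocorticoid score per library was higher in PAD+CKD than in PAD by 0.45 (permutation test, p = 0.0401, adjusted p = 0.822).

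Between PAD+CKD and CKD, glucocorticoid targets again had mostly higher means with both diseases, and the list was called only with the preset correlation. Of the 14 genes, 13 had higher means in PAD+CKD than in CKD (median 0.69, and 0.58 without CKD replicate 1), with CEBPD at 0.97 (SE 0.36), PER1 at 0.73 (SE 0.28) and GLUL, at 221 ± 232 TPM (n = 14) against 105 ± 49.1 TPM (n = 16), at 0.86 (SE 0.33). Adjusted over the list alone, 4 of them were higher, and 0 without CKD replicate 1. The glucocorticoid score averaged 0.343 ± 0.713 (n = 14) against −0.295 ± 0.638 (n = 16). The difference in means was 0.64 (permutation test, p = 0.00934, adjusted p = 0.467), and 0.51 (p = 0.0168) without CKD replicate 1. Extreme libraries weigh on these means: CKD replicate 1 scored −2.27, while the other 85 libraries ranged from −1.01 to 2.18. All 6 measured metallothionein genes, which bind zinc and copper, were higher (median 0.44), such as MT1E (0.79, SE 0.37), MT1X (0.69) and MT2A (0.56). IRS2 was above the CKD median in 14 of 14 libraries (0.91, SE 0.25) and passed when adjusted over its list alone. Its list was higher in 14 of 17 cases with a median of 0.08, which turned to −0.02 without CKD replicate 1 (8 of 17 higher), with SLC2A4 at 0.45 (0.21 without it) and PIK3R1 at 0.47.

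Many mitochondrial genes had higher means in PAD+CKD than in CKD, but CKD replicate 1 gave most of the difference. Complex I subunits were higher in 36 of 37 cases (median 0.18), and in 27 without it (median 0.05), such as NDUFS3 (0.35, SE 0.15; 0.13 without it), NDUFS7 (0.25; 0.13) and NDUFA8 (0.36; 0.12). All 28 fatty acid genes were higher (median 0.24), and 24 without it (median 0.07), with CD36 at 0.53 (SE 0.26; 0.24 without it), PPARA at 0.30 (0.15) and HADHA at 0.27 (0.13). Interferon response genes were lower in 20 of 21 cases (median −0.36), with OAS1 at −0.49 (−0.24 without it) and OAS3 at −0.43 (−0.18). Without CKD replicate 1, where 18 were lower, their median was −0.17 and the list was not called (adjusted p = 0.349). Of the key genes, PPARGC1A (0.45, SE 0.20), TRIM63 (0.80, SE 0.39; 0.52 without it), VEGFA (0.69, SE 0.28) and HIF1A (−0.26, SE 0.13; −0.15) had unadjusted p below 0.05, with an adjusted p of 0.332 when adjusted over the list alone.

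By limma, 0 of 16805 genes passed in PAD+CKD against CKD, and 955 had an unadjusted p below 0.05, 333 higher and 622 lower. With median-of-ratios scaling the split turned to 833 higher and 547 lower. The smallest p belonged to AC092718.4 (−1.09, SE 0.24; adjusted p = 0.333), CASP8AP2 (−0.40, SE 0.10), MSL2 (−0.40, SE 0.11), CDC42EP4 (0.80, SE 0.21) and RN7SL285P (−0.76, SE 0.21). The camera test called 25 of 50 lists, 21 up and 4 down, with adjusted p of 9.5e-15 for complex I, 1.4e-10 for fatty acid genes, 1.7e-10 for glucocorticoid targets, 1.1e-05 for interferon response, 0.00032 for insulin genes and 0.001 for metallothioneins. None was called with an estimated correlation, where the adjusted p was 0.258 for complex I, fatty acid genes, glucocorticoid targets and metallothioneins, 0.322 for insulin genes and 0.395 for interferon response.

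PAD and CKD muscle were compared with each other. Basement membrane genes were higher in PAD in 13 of 13 cases (median 0.38, and 0.20 without CKD replicate 1), among them COL18A1, at 23.5 ± 10.5 TPM (n = 32) against 16.3 ± 8.54 TPM (n = 16; 0.63, SE 0.20; 0.41 without that library), LAMA5 (0.38, SE 0.13; 0.23 without that library) and COL4A2 (0.57, SE 0.21; 0.34). Of these 13 genes 7 passed when adjusted over the list alone, and 0 without CKD replicate 1. Fibrillar matrix genes were higher in 29 of 30 cases (median 0.38, and 0.32 without it), with COL6A1 at 0.62 (SE 0.22; 0.35 without it), COL5A2 at 0.49 (SE 0.20), COL5A1 at 0.51 (SE 0.22) and COL3A1 at 0.77 (SE 0.34). Complex I subunits were higher in 37 of 37 (median 0.17), and in 32 without it (median 0.05), such as NDUFB1 (0.37; 0.15 without it), NDUFB9 (0.22; 0.10) and NDUFB3 (0.21; 0.11). ATP synthase subunits were higher in 15 of 15 (median 0.22), and in 12 without it (median 0.09). ATP5MC1 was at 0.35 (SE 0.11; 0.21 without it), ATP5F1C at 0.22 and ATP5PF at 0.27 (0.11), and 1 passed when adjusted over the list alone.

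Satellite cell and myogenic genes were higher in PAD than in CKD in 14 of 15 cases (median 0.26), but without CKD replicate 1, where 10 were higher, their median was 0.03, and the 2 genes that passed when adjusted over the list alone became 0. HEYL was at 0.45 (SE 0.15), MYMX at 0.43 (SE 0.15) and NOTCH3 at 0.38 (0.16 without it). The aryl hydrocarbon receptor senses compounds that include uremic solutes and tobacco smoke components, and all 12 genes of its list with kynurenine metabolism were higher in PAD (median 0.15), and 8 without CKD replicate 1 (median 0.08). CYP1B1, a target of the receptor, was at 0.44 (SE 0.18; adjusted p = 0.478 when adjusted over the key genes' list alone), CYP1A1 at 0.56 (SE 0.41) and AFMID at 0.15 (0.09 without CKD replicate 1).

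By limma, 0 of 16805 genes passed in PAD against CKD, and 876 had an unadjusted p below 0.05, 513 higher and 363 lower in PAD. The smallest p belonged to PAPOLG (−0.28, SE 0.07; adjusted p = 0.914), AC010457.1 (1.04), LYNX1 (0.51, SE 0.14), MTCL1 (0.29, SE 0.08) and MIER3 (−0.32, SE 0.09). The camera test called 23 of 50 lists, 19 up and 4 down, with adjusted p of 6.8e-15 for complex I, 1.0e-10 for fibrillar matrix, 3.4e-10 for ATP synthase, 3.0e-09 for basement membrane, 6.6e-05 for satellite cell genes and 0.0098 for the aryl hydrocarbon receptor list. No list was called with an estimated correlation (adjusted p = 0.350 for each list named). The satellite cell and myogenic regulators list was not called without the low-correlation libraries (adjusted p = 0.217). The aryl hydrocarbon receptor list was not called with no filter on low values (median 0.097, adjusted p = 0.173), nor with the library number covariate and CKD replicate 1 left out (adjusted p = 0.0506).

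**Figure D3:**
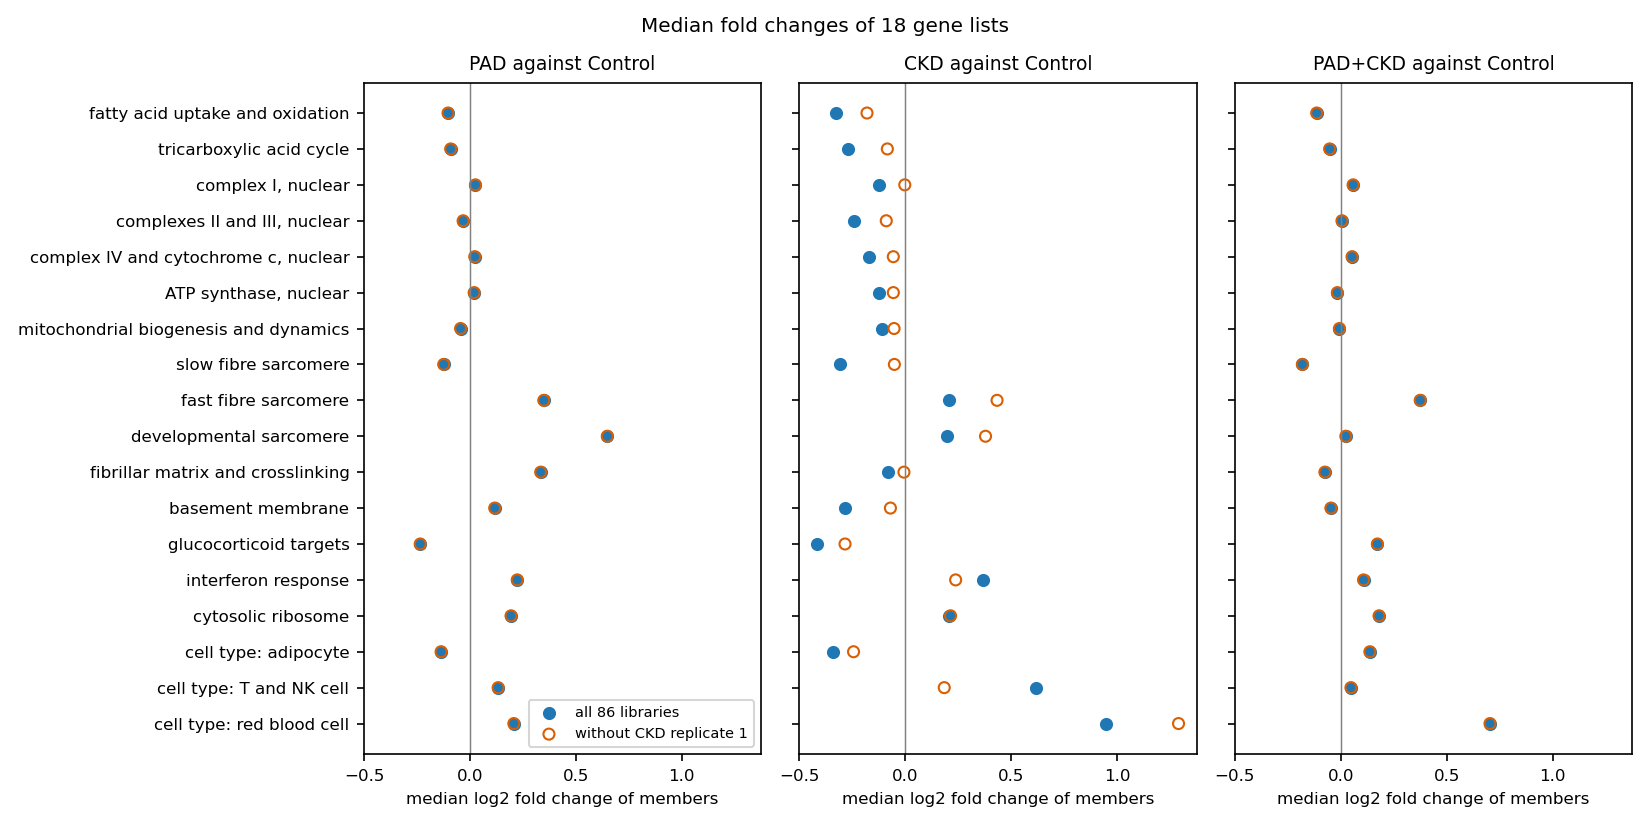
Median log2 fold change against Control (x axis) of 18 gene lists (y axis) in PAD, CKD and PAD+CKD; filled points use all 86 libraries and open points leave out CKD replicate 1. The fatty acid median was −0.10 in PAD, −0.33 in CKD (−0.18 without that library) and −0.11 in PAD+CKD.

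The interaction term asked whether the difference that goes with CKD depends on PAD, as (PAD+CKD minus PAD) minus (CKD minus Control). Glucocorticoid targets had the largest median of the lists called: 13 of 14 were positive (median 0.91, and 0.78 without CKD replicate 1). That is, most had lower means in CKD than in Control but higher means in PAD+CKD than in PAD. Most also had lower means in PAD than in Control, so low PAD values enter the term too. The list was not called in PAD+CKD against Control. These are contrasts of group means, which a few high or low libraries can move. KLF15 was at 1.40 (SE 0.39), GLUL at 1.39 (SE 0.41) and KLF9 at 0.81 (SE 0.28). Adjusted over the list alone, 8 of the 14 passed, and 2 without CKD replicate 1. Adipocyte marker genes were positive in 12 of 16 cases (median 0.65), and in 10 without it (median 0.60), with LPL at 1.34 (SE 0.38), LIPE at 0.78 (SE 0.24) and PLIN4 at 0.95 (SE 0.32), and 4 passed when adjusted over the list alone, 3 without that library. Fatty acid genes were positive in 27 of 28 (median 0.37), and in 25 without it (median 0.21), such as ACSL1 (0.90, SE 0.31), FABP3 (1.05, SE 0.38) and PPARA (0.57, SE 0.20). Interferon response genes were negative in 21 of 21 (median −0.55, and −0.37 without it), with IFIT2 at −0.55 (SE 0.19) and MX1 at −0.76 (SE 0.28).

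By limma, 0 of 16805 genes passed for the interaction, and 1779 had an unadjusted p below 0.05, 370 positive and 1409 negative, or 1130 positive and 909 negative with median-of-ratios scaling. The smallest p belonged to DSN1, a kinetochore protein (−0.62, SE 0.15; adjusted p = 0.326), CDC42EP4 (1.13, SE 0.27), IRS2 (1.30, SE 0.31), AL391840.1 (−1.17, SE 0.29) and RPARP-AS1 (−0.67, SE 0.17). The camera test called 24 of 50 lists, 20 up and 4 down, with adjusted p of 2.6e-16 for fatty acid genes, 2.3e-13 for glucocorticoid targets, 5.9e-08 for adipocyte genes and 3.4e-07 for interferon response. With an estimated correlation none was called, and the adjusted p was 0.159 for glucocorticoid targets, 0.240 for fatty acid genes, 0.241 for adipocyte genes and 0.375 for interferon response. When the 5 libraries with low correlations to the rest were left out, fatty acid genes (median 0.24) and glucocorticoid targets (median 0.90) were called with an estimated correlation, both with an adjusted p of 0.031.

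The 13 mitochondrially encoded protein genes took 41.0% ± 7.09 (SD, n = 24) of TPM in Control, 39.3% ± 5.76 (n = 32) in PAD, 38.8% ± 8.70 (n = 16) in CKD (37.3% ± 6.53 without CKD replicate 1, n = 15) and 40.7% ± 5.94 (n = 14) in PAD+CKD. No difference between 2 groups passed the test (two-sided permutation tests, 100000 resamples, adjusted p from 0.764 to 0.896 over 6 pairs). CKD was below Control by −2.15 percentage points (p = 0.398), and by −3.65 without CKD replicate 1 (p = 0.115, adjusted p = 0.478), and PAD+CKD was above CKD by 1.85 (p = 0.510), and by 3.35 without it (p = 0.159). Differences in medians were larger but did not pass the permutation test either. They were −5.86 for CKD against Control (p = 0.0640, adjusted p = 0.384) and 5.26 for PAD+CKD against CKD (p = 0.177, adjusted p = 0.419). MYH7, the slow myosin heavy chain, made up 70.9% ± 15.4 of the TPM of the 3 adult limb myosins MYH7, MYH2 and MYH1 in Control, 63.8% ± 17.9 in PAD, 64.6% ± 15.9 in CKD and 64.9% ± 13.1 in PAD+CKD. The share of slow myosin was lower than in Control by −7.07 percentage points in PAD (p = 0.127), −6.36 in CKD (p = 0.214; −7.42 without CKD replicate 1) and −5.98 in PAD+CKD (p = 0.230), each within the spread between libraries (adjusted p = 0.461).

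Fold changes of the 3 disease groups were correlated across genes, and all 3 share the Control libraries. Across 16805 genes, which are not independent replicates, Pearson's r was 0.606 between PAD and CKD. In 100 regroupings without any effect the shared controls alone gave a median r of 0.477 (0.159 to 0.717), and with the controls split into 2 sets of 12 the observed r was 0.268 in the median. The covariance was 0.0195 against 0.0104 simulated, a difference of 0.00911. Between PAD and PAD+CKD r was 0.469 (0.489 simulated; 0.117 with split controls; covariance 0.0124 against 0.0106), and between CKD and PAD+CKD it was 0.412 (0.41 simulated; 0.133 with split controls; covariance 0.014 against 0.0106). All 3 values of r lay inside the range of the regroupings.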

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

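The 3 tests of the library that stood apart, the fits without it, the test of it as a source of the fatty acid difference and the splits of those fits, as well as the refits of the splits with most calls, were chosen only after the results were seen, and the other tests in this part were planned.

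For 24 lists the interaction term of the list genes differed from that of the other genes, by the camera test with the preset correlation. These lists were set against an all-gene median of −0.101, so a list with a median near 0 can be called up. None of these passed with an estimated correlation in all 86 libraries, while fatty acid genes and glucocorticoid targets did without the 5 low-correlation libraries. Median log2 values above 0 were 0.37 for fatty acid genes, 0.91 for glucocorticoid targets, 0.65 for adipocyte genes, 0.147 for complex I, 0.269 for complexes II and III, 0.221 for complex IV, 0.154 for ATP synthase, 0.146 for mitochondrially encoded proteins and 0.291 for the tricarboxylic acid cycle. They were 0.0861 for glycolysis, 0.122 for mitochondrial biogenesis, 0.258 for slow fibre genes, 0.133 for atrophy genes, 0.0674 for angiogenesis, 0.278 for metallothioneins, 0.0588 for insulin genes, 0.154 for immediate early genes, 0.156 for endothelial and 0.110 for pericyte genes. Values below 0 were −0.55 for interferon response, −0.226 for cytosolic ribosome, −0.809 for T and NK cells and −0.769 for keratinocyte genes. The hypoxia list had a median of −0.00152, although its mean, 0.0868, lay above 0 and it was called up relative to the other genes. Without CKD replicate 1 the median turned to −0.0122 for slow fibre, −0.121 for glycolysis, −0.00475 for insulin, −0.00954 for endothelial and −0.0523 for pericyte genes, and lists not called were T and NK cells (−0.320, adjusted p = 0.562), glycolysis (adjusted p = 0.246) and keratinocyte genes (−0.685, adjusted p = 0.0684). Medians that shrank by more than 1.5 times without it were 0.00565 for complex I, 0.0866 for complexes II and III, 0.0791 for complex IV, 0.0814 for ATP synthase, 0.137 for the tricarboxylic acid cycle, 0.206 for fatty acid, 0.0232 for mitochondrial biogenesis and 0.0318 for atrophy genes.

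CKD replicate 1 correlated with the other libraries at a median of at most 0.614 per group, against 0.828 for the lowest of the other 85. Loss of RNA quality alone is argued against by the T and NK cell list, which was higher than in the other CKD libraries by a median log2 ratio of 6.28 with a lower quartile of 5.83. A loss of quality beside another cause is not excluded. All mitochondrially encoded genes took 80.9% of TPM in this library, against 62.5% in the next highest. Its 19930 genes above 0 were the fewest of all libraries. A label exchanged between 2 of the 4 groups is argued against by the same correlation of 0.614, since it lay below every library of every group. RNA of T and NK cells beside muscle RNA is a candidate explanation: the score of that list was 5.91, against at most 1.26 elsewhere, while median log2 ratios were −3.84 for slow fibre, −4.42 for fast fibre, −3.73 for calcium handling and −3.84 for glycolysis genes. Whether such cells were in the muscle or came from a mixed sample was not tested. Macrophage genes went both ways: 6 of 18 were above the median of the other CKD libraries, such as C1QA (14.4 against 4.82 TPM) and MRC1 (1.81 against 0.90 TPM), while CD163 and CD68 were at 0 TPM. Genes of dividing cells were highest in this library too, with MKI67 at 9.55 TPM against at most 0.757 elsewhere, TOP2A at 15.7 against 1.81 and UBE2C at 35.9 against 3.34, which does not tell these origins apart. The filter itself required 1 TPM in at least 14 libraries, so the 8 list genes were not kept through this library alone.

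The fatty acid uptake and oxidation list was lower in CKD than in Control by a median of −0.33. The library apart as the whole cause is argued against by a median of −0.18 without it, where the score differed at p = 0.0168 (adjusted p = 0.377 over 50 lists). A different share of adipose and connective tissue, as far as the 2 list scores measure it, is argued against by a median of −0.19. That fit had both scores as covariates and left out that library (permutation p = 0.0101). The scores only stand in for the tissue share and were not checked against it, so such a difference is not excluded. The order of collection cannot be told apart from CKD, since with the library number as covariate the median was −0.112 (p = 0.249) and the numbers only stand in for that order. A difference that goes with kidney disease itself stays open as an untested hypothesis.

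Other splits of the same libraries into groups of the same sizes were drawn, 100 per comparison with the real one. For genes called, 4 splits in CKD against Control gave at least the real 1 (highest other 8). That share lies just under 0.05 but was not adjusted over the comparisons. The call was also lost in other settings, such as without CKD replicate 1, so chance is not excluded. In the other 6 comparisons the real count was 0, which all 100 splits reached, with a highest other of 0 in PAD against Control, PAD+CKD against Control and the interaction, 1 in PAD+CKD against PAD, 1217 in PAD+CKD against CKD and 165 in PAD against CKD. The splits with 1217 and 165 calls are the largest of those drawn, and both kept CKD replicate 1 in the CKD set. Whether a structure of the samples lies behind them stays open. Refitted with the same split, the 165 became 0 without the 5 low-correlation libraries, 4 of which lay in the CKD set, but 625 without CKD replicate 1 alone. The 1217 became 104 without CKD replicate 1, 98 with the library number covariate and 1627 without the low-correlation libraries, so what that split separates stays open. For genes at unadjusted p below 0.05 chance cannot be excluded in any of the 7: as many came in 6 splits for PAD against Control (real 1454, highest other 3638), 14 for CKD against Control (1755, 3189), 41 for PAD+CKD against Control (491, 1609), 26 for PAD+CKD against PAD (712, 3479), 64 for PAD+CKD against CKD (955, 5231), 40 for PAD against CKD (876, 4577) and 6 for the interaction (1779, 2146).

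For lists called at the preset correlation in CKD against Control, only the real one of 100 splits reached 33 (highest other 27). The same held without CKD replicate 1 (1 split, real 29, highest other 26). This is the smallest share that 100 splits can give, and it was not adjusted over the patterns examined. With an estimated correlation no list was called there. Chance is therefore less likely for this count but not excluded. Nor can it be excluded for the other 6 comparisons. There 30 splits reached the real 15 in PAD against Control (highest other 26), 96 the 4 in PAD+CKD against Control (22) and 19 the 17 in PAD+CKD against PAD (23). For the rest, 6 reached the 25 in PAD+CKD against CKD (26), 10 the 23 in PAD against CKD (27) and 7 the 24 of the interaction (26). With adipocyte and fibroblast covariates and without CKD replicate 1, 2 splits gave at least the real 418 genes in CKD against Control. Only 4 other splits called any, but the highest other gave 1895. Whether a structure of the samples lies behind that split stays open. It still called 1878 genes with the library number covariate added, so the library number does not account for it. Without the low-correlation libraries it called 2501. That refit cannot decide, because 0 of those libraries lay in either of the 2 sets compared.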

How the results depend on the processing

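The fits without CKD replicate 1, alone or combined with covariates or scaling, those of protein-coding genes only and the list scores per library were chosen only after the results were seen, and the other alternatives were planned. All settings fixed beforehand were run, except that the interaction has no fit of only 2 groups. No paired analysis was possible because replicate numbers follow the order of accession and pair no samples. Depth is unknown in TPM, so no limit from counting error can be given.

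The 7 shares that turned lay within the spread between libraries. The mitochondrially encoded share in PAD against CKD was −0.508 points with all mitochondrially encoded genes, and in PAD+CKD against Control 0.609 without the low-correlation libraries. The slow myosin share was −2.32 in PAD+CKD against PAD, −1.79 in PAD+CKD against CKD and 0.528 in PAD against CKD by medians, and the last was 0.759 without the low-correlation libraries and 0.350 without CKD replicate 1.

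With limma, the 1 gene called in CKD against Control became 0 with no filter, array quality weights, only the 2 groups, the library number covariate (also with CKD replicate 1 left out), the sex chromosome gene covariate, the low-correlation libraries left out or without CKD replicate 1. It became 2 with median-of-ratios scaling, 306 with the adipocyte and fibroblast list covariates, 418 with CKD replicate 1 also left out and 2 with scaling added. The adjusted p of AC131097.2 ranged from 0.00931 to 0.971, and its log2 fold change from −2.71 to −1.58. In PAD against Control 1 gene, AL080248.1, was called with array quality weights (adjusted p = 0.00443) and with the sex chromosome gene covariate (0.0235), and in PAD+CKD against PAD 1, AC092718.4, with the library number covariate and CKD replicate 1 left out (0.0449). The cause was not tested. In PAD against Control, 84.8% of genes at unadjusted p below 0.05 were higher. It was 70% with mitochondrially encoded genes, which are among the most abundant, removed, in a test chosen after the excess was seen, which leaves open whether the share of TPM that abundant genes take is the source. The 50.4% with median-of-ratios scaling decides nothing, because that scaling centres the fold changes.

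With an estimated correlation 0 lists were called in each of the 7 comparisons, and list scores per library called 0 in each of the 6 pairs, with and without CKD replicate 1. An estimated correlation together with other settings called 2 lists for the interaction without the low-correlation libraries. With the adipocyte and fibroblast covariates and CKD replicate 1 left out it called 5 lists in CKD against Control and 4 for the interaction, 2 of each being the covariates themselves, and with scaling added 1 in each (mitochondrial biogenesis and dynamics, adjusted p 0.0345 and 0.0316). With the preset correlation the 4 lists called in PAD+CKD against Control became 1 with median-of-ratios scaling, 8 without mitochondrially encoded genes, 7 with array quality weights, 10 with the library number covariate (12 with CKD replicate 1 left out), 14 without the low-correlation libraries and 9 with protein-coding genes only. The 17 in PAD+CKD against PAD became 8 with the adipocyte and fibroblast covariates and CKD replicate 1 left out, with or without scaling. The cause was not tested.

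Medians of the lists named kept their direction and call in 742 cases, lost the call in 61 and turned in 18. In CKD against Control the turned medians were 0.00560 for adipocyte genes (with that list as a covariate and CKD replicate 1 left out), and −0.00541 for T and NK cells and 0.00415 for complex I with the library number covariate and CKD replicate 1 left out. In PAD against CKD, satellite cell genes turned to −0.0101 with array quality weights, −0.0602 without the low-correlation libraries and −0.0642 with the adipocyte and fibroblast covariates and CKD replicate 1 left out. With these covariates and all libraries the PAD against CKD medians were −0.00193 for fibroblast, −0.0794 for macrophage and −0.0739 for complement genes. With CKD replicate 1 also left out they were −0.0236, −0.0411 and −0.0485, and that of pericyte genes was −0.0407. In PAD+CKD against CKD, insulin genes turned to −0.00706 with array quality weights, −0.0440 without the low-correlation libraries, −0.0206 without CKD replicate 1, −0.0466 with the adipocyte and fibroblast covariates and −0.0228 with the library number covariate, both with CKD replicate 1 left out. Of the named genes none turned: 3032 cases stayed on the same side of the threshold, 17 gained a call and 8 lost it, the last all AC131097.2.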

Other observations

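The correlation between developmental sarcomere and matrix genes, and the reading of its counterpart with fatty acid genes, were chosen only after the results were seen, as were the values without CKD replicate 1, and the other tests in this part were planned.

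Lists of vessel, stromal and resident immune cell genes had higher medians in PAD than in CKD muscle, but most of them did not keep this with the adipocyte and fibroblast list covariates. Endothelial markers were higher in 15 of 17 cases (median log2 fold change 0.24), and in 13 without CKD replicate 1 (median 0.08), such as PECAM1 (0.32, SE 0.13), CLDN5, a tight junction protein (0.48, SE 0.22), and VWF (0.33, SE 0.15; 0.11 without it). Pericyte and smooth muscle markers were higher in 15 of 15 (median 0.24), and in 9 without it (median 0.16), with PDGFRB at 0.36 (SE 0.16; 0.17 without it) and ACTA2 at 0.51 (SE 0.26). Markers of fibroblasts and fibro-adipogenic progenitors were higher in 17 of 17 (median 0.28), for example THY1 (0.71, SE 0.30) and FBLN2 (0.35, SE 0.17; 0.20 without it). Macrophage markers were higher in 17 of 18 (median 0.21), among them VSIG4 (0.49, SE 0.23) and the scavenger receptor CD163 (0.42, SE 0.23). Complement genes were higher in 11 of 12 (median 0.30), such as C7 (0.51, SE 0.22) and C3 (0.46, SE 0.25). By camera with the preset correlation the adjusted p was 3.1e-05 for endothelial, 0.00019 for pericyte, 2.7e-05 for fibroblast and 0.0044 for macrophage and complement genes. The adjusted p with an estimated correlation was 0.350 for the first 3 lists, 0.706 for macrophage and 0.515 for complement genes, and 0 genes of these lists passed when adjusted over the list alone. With the adipocyte and fibroblast list covariates the preset call was lost for macrophage (median −0.0794, adjusted p = 0.929), complement (−0.0739, 0.926) and fibroblast genes (−0.00193, 0.249), the last itself a covariate. It was kept for endothelial (median 0.157) and pericyte genes (median 0.063), and lost for the pericyte list with CKD replicate 1 also left out (−0.0407, adjusted p = 0.0660).

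In CKD against Control with the adipocyte and fibroblast list scores as covariates, a planned setting, the genes with the smallest p among the 306 called by limma were AC131097.2, which fell (−2.22, adjusted p = 0.00931), and, all higher, ZNF143 (0.41, adjusted p = 0.0212), GGT1 (0.57, 0.0212), TRIP6 (0.45, 0.0225), GPATCH1 (0.48, 0.0225) and YIPF5 (0.40, 0.0225). FABP3 (−1.05, adjusted p = 0.0384) and ACSL1 (−0.79, 0.0481) also fell in this setting. With CKD replicate 1 left out as well FABP3 was at −0.81 (adjusted p = 0.0401) and ACSL1, no longer called, at −0.62 (0.0594), and with scaling added neither was called (0.0872 for both). ZNF143 was at 5.23 ± 1.36 TPM (n = 16) in CKD and 3.76 ± 0.757 TPM (n = 24) in Control. The choice of these genes was made after their values were seen, and these covariates with median-of-ratios scaling and CKD replicate 1 left out called 2 genes, ZNF143 not among them.

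Developmental sarcomere genes varied between libraries of every group. One hypothesis was that matrix genes vary with them within groups. Pearson's r of the list scores was 0.726 in Control (permutation p = 7e-05, adjusted p = 0.00028 over 8 relations; Spearman's rho 0.682, p = 0.00035), 0.741 in PAD (p = 1e-05, the smallest the permutations can give, adjusted p = 8e-05; rho 0.710, p = 4e-05), 0.646 in CKD (p = 0.00655, adjusted p = 0.0131; rho 0.624, p = 0.0107) and 0.373 in PAD+CKD (p = 0.187, adjusted p = 0.213; rho 0.169, p = 0.565). Without the 2 libraries farthest from the median r was 0.566, 0.652, 0.479 and −0.075 in the same order, and without CKD replicate 1 it was 0.530 in CKD (p = 0.0428). The data may therefore hold such a relation in 3 groups, while the 14 PAD+CKD libraries leave it open with 0.373.

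A planned hypothesis was that fatty acid genes vary against developmental sarcomere genes. Pearson's r was −0.263 in Control (p = 0.216, adjusted p = 0.216; rho −0.239, p = 0.259), −0.327 in PAD (p = 0.0683, adjusted p = 0.0911; rho −0.374, p = 0.0367), 0.495 in CKD (p = 0.0471, adjusted p = 0.0754; rho 0.118, p = 0.667) and −0.706 in PAD+CKD (p = 0.00517, adjusted p = 0.0131; rho −0.477, p = 0.0859). Without the 2 farthest libraries r was −0.171, −0.432, −0.167 and −0.158, so the relation in PAD+CKD rests on those libraries, and the CKD value fell to 0.0086 (p = 0.976) without CKD replicate 1. The bound set beforehand counted a p of 0.05 or more, or an r above 0, in at least 2 groups against the hypothesis, and these values meet it. That bound was wrong, because a p that misses the threshold excludes nothing and the only r above 0 rested on 1 library, so the hypothesis is left undecided, a reading chosen after the values were seen.

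A further planned hypothesis was a larger spread of the developmental sarcomere score in PAD than in Control. The mean distance from the group median was 1.01 in PAD and 0.953 in Control, a difference of 0.0533 (two-sided permutation p = 0.816), which leaves the question open.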
